A study of Mus musculus with 6 samples.

How the data were processed

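RNA was measured by sequencing in 6 mouse libraries, 3 from heart and 3 from gastrocnemius, the large calf muscle. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a stranded mRNA kit (TruSeq Stranded mRNA). The submitters' processing notes name Trimmomatic, HISAT2 and HTSeq without versions or settings, and name the human build hg38, while every gene identifier in the table is a mouse Ensembl identifier. The deposited values are raw read counts per gene, 1 column per library, per the file headers, and all of them were whole numbers. Whether the counting used strand is not given in the sources used here, so reads from a gene and an overlapping gene on the opposite strand cannot be told apart.

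The name, biotype and position columns of the table do not belong to the gene identifiers of their rows: 0 of 55401 rows paired an identifier with its own symbol. The counts follow the identifiers, since Myh6 (the cardiac alpha myosin heavy chain) had 349797 counts by identifier and 0 by the symbol column, and Myh4 (a fast skeletal myosin) had 1833300 and 18. Symbols were therefore taken from a gene name table by identifier, with 55141 identifiers matched and 260 unmatched, which held 0.026% of all counts. Positions, biotypes and transcript lengths came from GENCODE M21 on GRCm38. The table's own name and position pairs matched that annotation within 5000 bp for 53331 of 53399 names (99.87%), so those columns follow that mouse build.

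The titles open with a letter, C, M or Z, whose meaning is not given in the sources used here. Each letter has 1 library in each tissue, and replicate numbers 1, 2 and 3 were given to letters M, Z and C in both tissues. No label says whether the libraries came from separate animals, so p-values measure only the spread between these samples. Each title also ends in a number that is not explained. Within every title letter this number differs between heart and gastrocnemius, which does not settle whether those libraries are paired. The tissue comparison had 3 libraries on each side and counted letter differences as spread. Letters were compared with tissue and letter as additive terms, which takes a difference to be equal on the log scale in both tissues and leaves 2 residual degrees of freedom. An interaction of letter and tissue could not be tested. Within a tissue each letter is 1 library, so those differences have no replicate check and no p-value.

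Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter (minimum count 10) and a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. An SE given for a log2 fold change is its absolute value divided by the square root of the test's F statistic. It is not a standard error of the fitted value, and for genes with few counts it can be smaller than the counting error. The filter left 16628 of 29923 genes with a count. Gene lists with at least 5 measured members were tested against all other genes with camera of limma 3.58.1, with its preset correlation of 0.01 and again with a correlation estimated from the data, on log2 CPM with a prior count of 2. Single libraries were compared as the log2 ratio of TMM-scaled CPM plus 1 for genes with at least 10 CPM in the higher library. A list's median log2 ratio in a library pair was placed as a percentile among 10000 random lists of equal size matched on expression, for lists with at least 3 measured members. A gene at 0 counts in every library of a tissue was given as a bound against a floor of 3 counts per library (0.140 to 0.201 CPM). Such a bound compares counts summed over a tissue's libraries, each sum divided by the summed effective library sizes, so it is not the ratio of mean CPM to the floor. A gene with 1 to 3 counts was given as a ratio with its 95% counting interval. Intervals and floors cover counting error only.

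There were 45 lists, fixed before the data were examined. They covered the cardiac sarcomere, the slow-fibre and shared cardiac sarcomere, fast-fibre sarcomere and calcium handling, cardiac transcription factors, skeletal myogenic factors, cardiac ion channels and junctions, skeletal excitation-contraction coupling, cardiac stress and hypertrophy, fatty acid oxidation, glycolysis and glycogen use, the nuclear-encoded respiratory chain, the tricarboxylic acid cycle, mitochondrially encoded genes, muscle atrophy, the denervation response, glucocorticoid targets, the circadian clock, extracellular matrix, inflammation, interferon response, immediate early genes, heat shock proteins, the unfolded protein and integrated stress response, the oxidative stress response, PPAR and fasting targets, cell cycle, proteasome and cytosolic ribosomal proteins. Marker lists covered atrial and ventricular cardiomyocytes, endothelial cells, fibroblasts, smooth muscle and pericytes, macrophages, neutrophils, lymphocytes, erythroid cells, white and brown adipocytes, Schwann cells and nerve, satellite cells, epicardial and mesothelial cells, tendon, lung epithelium and sex (Xist and Y-linked genes).

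Genes named for the tissue comparison were the 10 with the largest log2 fold change in each direction among those past the threshold, with a mean of at least 10 CPM in the higher tissue and no overlap between the tissues' libraries. Up to 4 members of each list were added, those with the largest change past the threshold at a mean of at least 1 CPM, or the 2 most highly expressed where none passed. For letters the rule named up to 10 genes in each direction or, with fewer than 5 past the threshold, the 5 with the smallest unadjusted p. For single libraries it named the 5 genes furthest apart in each direction and up to 4 members of each list outside the central 95% of random lists. Pseudogenes and genes without a proper name were passed over, and some genes that these rules name are not reported here. In the tissue comparison, Myh6, Acta1, Scx, Fmod, Thbs4 and Sdc4 were named after their values were seen.

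The alternatives tried were DESeq2 1.42.0 (its size factors, and its own Wald test), limma-trend, no filter, a filter of 10 CPM in 3 libraries, mitochondrially encoded genes left out before scaling, the title letter as a block, each library left out in turn, a pseudocount of 5 CPM, a minimum of 1 CPM and CPM by total count. Removal of the transcript length trend, random lists matched also on length, and omission of both letter C libraries were chosen after the data were seen. The tests were run on simulated counts for the 16628 genes, 200 of them changed. In the tissue design 5% of 2-fold and 70% of 4-fold changes were called, with 10 unchanged genes called. The adjusted threshold is stricter when few genes change, and 8435 genes passed between the real tissues. These shares are therefore not those of the real tissue comparison. In the letter design 12% of 2-fold and 67% of 4-fold changes were called, with 21 unchanged genes called. Camera called the planted 2-fold list and 0 of 36 others in both designs, and with an estimated correlation it called that list in the tissue design only. The planted list stood at percentile 100 in the single-library step, where 2 of the 36 other lists lay outside the central 95%. Each gene was simulated independently of the others, so no list held correlated genes. These list checks therefore cannot show how often lists of correlated genes are called. Counting noise alone put 0 unchanged genes among 8793 at least 2-fold apart. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.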

Results

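Polyadenylated RNA was sequenced in 6 mouse libraries, 3 from heart and 3 from gastrocnemius, the large fast calf muscle. In each tissue 1 library carried each of the title letters C, M and Z, whose meaning the labels do not give. The heart libraries held 17314013 counts for letter C, 17229514 for M and 15674456 for Z, and the gastrocnemius libraries 16947579, 17387098 and 17451679 for the same letters. Of 29923 genes with a count, 16628 were tested, 13448 of them protein coding. Mitochondrially encoded genes took 21.5% to 26.8% of counts in the heart libraries and 8.99% to 12.0% in the gastrocnemius libraries. Xist, the transcript of the inactive X chromosome, had 2771 to 8280 counts per library, and 4 Y-linked genes had 0 counts in all 6.

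The title of the series names heart and gastrocnemius muscle and no further question. The heart libraries were set apart by natriuretic peptides, cardiac sarcomere proteins and cardiac transcription factors. Nppb, the B-type natriuretic peptide gene (ENSMUSG00000029019, chromosome 4: 147985788 to 147987205 on GRCm38), stood at 506 ± 388 CPM in heart (SD, n = 3). It had 0 counts in gastrocnemius, which makes it at least 2409-fold higher in heart (edgeR adjusted p = 2.80e-04). Mybpc3, the cardiac myosin-binding protein (ENSMUSG00000002100, chromosome 2: 91118144 to 91136516), had 1323 ± 217 CPM in heart and 3 counts in gastrocnemius. Its ratio was 19850 with a counting interval of 6792 to 96260, and its log2 fold change was 14.14 (edgeR adjusted p = 3.66e-06). Its SE of 0.44, taken from the F statistic, does not cover that counting error. Nppa, the A-type natriuretic peptide gene, had 6109 ± 2412 CPM in heart and 0.481 ± 0.0894 in gastrocnemius, a log2 fold change of 13.61 (SE 0.66). Tnni3, the cardiac troponin I gene, had 3063 ± 1171 CPM in heart with a log2 fold change of 12.28, and the desmosomal gene Dsp had 683 ± 98.2 CPM with 12.27. Of genes at 0 counts in gastrocnemius, the transcription factor Tbx20 was at least 570-fold higher in heart, the potassium channel gene Kcnj5 at least 516-fold and the cardiac leucine-rich repeat gene Lrrc10 at least 457-fold. Mybphl was at least 307-fold higher, with 56.6 ± 50.4 CPM across the heart libraries, and Hand2 at least 256.5-fold.

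Fast myosins and their partners set gastrocnemius apart. Myh4, the fastest adult myosin heavy chain gene (ENSMUSG00000057003, chromosome 11: 67238029 to 67260446), had 40365 ± 12269 CPM in gastrocnemius and 1.26 ± 2.14 in heart (SD, n = 3), where 80 of its 81 counts came from the letter M library. Its log2 fold change of heart over gastrocnemius was -14.91 with SE 1.82 (edgeR adjusted p = 3.94e-04). Myh1, the IIx myosin gene, had 5454 ± 1772 CPM and a log2 fold change of -15.20. Myh2, the IIa myosin gene, had 2196 ± 1215 CPM and 3 counts in heart, a ratio of 41560 with a counting interval of 14220 to 201500. Myhas, which lies in the myosin cluster and overlaps Myh1 on the opposite strand, had 1138 ± 415 CPM and a ratio of 21700 (7423 to 105200). The fast troponin C gene Tnnc2 had 8298 ± 1389 CPM with a log2 fold change of -14.68, and the slow-type myosin-binding gene Mybpc1 had 2624 ± 627 CPM with -14.52. At 0 counts in heart, the myogenic factor Myf6 was at least 1426-fold higher in gastrocnemius, Igfn1 at least 1133-fold, Tmem233 at least 1111-fold and the Z-disc gene Myoz3 at least 887-fold. Myosin genes of this cluster share sequence, so reads of close copies cannot be fully told apart. The same holds for genes overlapping on opposite strands: Gm13054 held 289903 counts beside 356960 for Nppa, Ube2c 379212 beside 379112 for Tnnc2, and Myhas 52128 beside 248803 for Myh1. Mybphl, Hand2, Dsp, Mybpc1, Pln, Ryr1 and Myh7 overlap such a gene as well.

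In all, 8435 of 16628 genes (50.7%) passed an edgeR adjusted p of 0.05. Of these, 4570 were higher in heart and 3865 in gastrocnemius, and 3923 and 2553 of them differed at least 2-fold, 324 and 241 at least 32-fold. DESeq2 called 8861 genes and limma-trend 8526. The libraries of the tissues did not overlap for 10081 genes (60.6%), where chance gives 10% for 3 against 3. On the log2 scale, correlations across genes, which are not independent replicates, were 0.945 to 0.984 within a tissue and 0.705 to 0.765 between tissues.

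**Figure D1:**
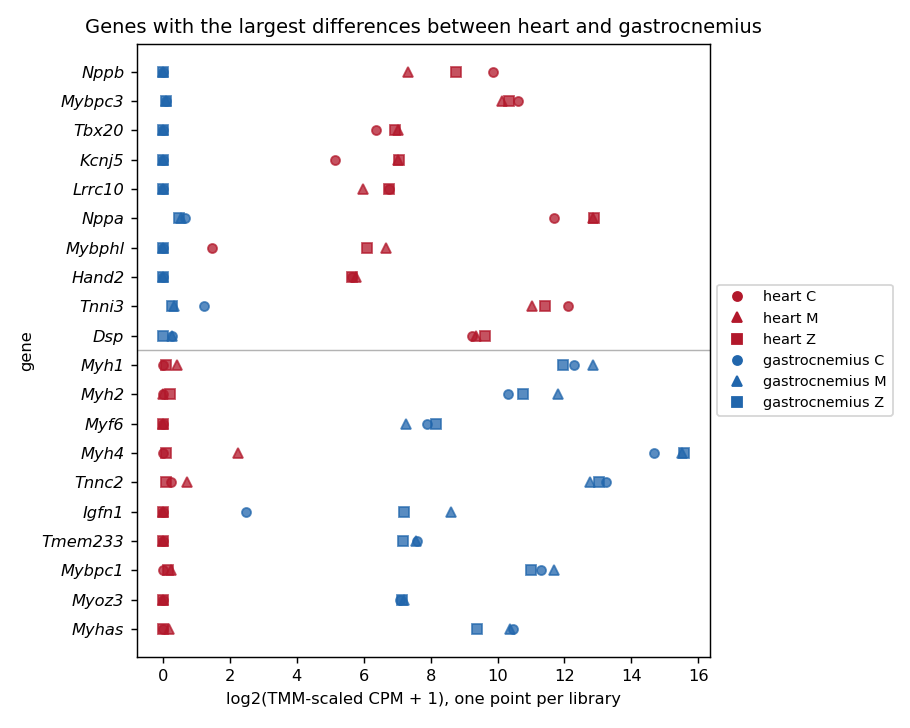
Log2 of TMM-scaled CPM plus 1 (x axis) for the 20 genes furthest apart between the tissues (y axis), with 1 point per library and the marker shape giving the title letter. Heart genes such as Nppa (6109 CPM on average) lie to the right in red and near 0 in gastrocnemius, and Myh4 (40365 CPM) and the other genes under the line show the opposite order.

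Contractile programs split by tissue. All 9 measured cardiac sarcomere genes were higher in heart, among them Tnnt2 (log2 11.07), Mylk3 (9.57) and Myh6, the alpha myosin heavy chain gene, at 5908 ± 2128 against 135 ± 117 CPM (5.45). Myl4 of this list did not pass with the title letter as a block (adjusted p = 0.165). The list's median was 8.55 (camera adjusted p = 1.03e-06; adjusted p = 0.138 with an estimated correlation). All 15 fast-fibre sarcomere and calcium handling genes were higher in gastrocnemius, with a median of -13.1 (camera adjusted p = 9.83e-15; adjusted p = 0.112 with an estimated correlation). Of the 10 slow-fibre and shared cardiac sarcomere genes, 7 were higher in heart, including Myl2 (4.55), Casq2 (4.24) and Myl3 (4.17), and 3 in gastrocnemius, including the slow troponin I gene Tnni1 (-4.87). That list was not called by camera (adjusted p = 0.131). Cardiac stress and hypertrophy genes were higher in heart for 6 of 9, with Ankrd1 at 9.32 and Timp1 at 6.66, lower for 2, with the skeletal actin gene Acta1 at -6.47, and not past the threshold for 1. Their median was 4.46 (camera adjusted p = 0.0281; adjusted p = 0.378 with an estimated correlation). Without the letter C heart library Timp1 fell to 4.05, still called, and DESeq2 gave it no adjusted p.

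Transcription factors and calcium or ion channel genes followed the same split. All 8 cardiac transcription factors were higher in heart, with Nkx2-5 at least 68.6-fold and Gata4, with 1 count in gastrocnemius, at a ratio of 2265 (406 to 89490). Their fitted median was 10.5, or 7.33 with genes at 0 set to their bounds (camera adjusted p = 3.36e-07; adjusted p = 0.112 with an estimated correlation). All 9 skeletal myogenic factors were higher in gastrocnemius, with Myog at least 180.5-fold, Myod1 at least 70.6-fold and Tbx15 at -11.46. The fitted median was -8.23, or -6.89 with bounds (camera adjusted p = 1.36e-07; adjusted p = 0.112 with an estimated correlation). Cardiac ion channels and junctions were higher in heart for 14 of 15, and for 15 when adjusted over the list alone, led by the ryanodine receptor Ryr2 (10.83), phospholamban Pln (10.77) and Kcnip2 (9.08). The median was 6.03 (camera adjusted p = 2.22e-09; adjusted p = 0.138 with an estimated correlation). All 14 skeletal excitation-contraction coupling genes were higher in gastrocnemius, among them Ryr1 (-13.03), Cacng1 (-11.69) and Jsrp1 (-10.09). Their median was -6.99, or -6.73 with bounds (camera adjusted p = 4.68e-11; adjusted p = 0.11 with an estimated correlation). Denervation response genes, which include acetylcholine receptor subunits and developmental myosins, were higher in gastrocnemius for 10 of 11. Myh3, with 1 count in heart, had a ratio of 6751 (1211 to 266700), Chrnd was at least 20.4-fold higher, and Myh8 stood at -10.85. The median was -7.03, or -5.80 with bounds (camera adjusted p = 2.69e-06; adjusted p = 0.11 with an estimated correlation).

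Fuel genes also separated the tissues. Fatty acid oxidation genes were higher in heart for 16 of 21, and for 17 when adjusted over the list alone, with the carnitine transferase Cpt1a at 2.56, Ech1 at 2.49, the lipid carrier Fabp3 at 2.12 and Cd36 at 1.93. Their median was 1.18 (camera adjusted p = 2.55e-05; adjusted p = 0.489 with an estimated correlation). Glycolysis and glycogen use genes were higher in gastrocnemius for 16 of 17, with the phosphorylase kinase subunits Phka1 (-5.38) and Phkg1 (-4.66) and aldolase Aldoa (-3.93) in front. Their median was -2.77 (camera adjusted p = 2.22e-09; adjusted p = 0.11 with an estimated correlation). PPAR and fasting targets were higher in heart for 8 of 12 (9 when adjusted over the list alone), among them Ucp2 (3.10) and Acot1 (2.39), and lower for 2. Their median was 1.74 (camera adjusted p = 0.00665; adjusted p = 0.32 with an estimated correlation). Mitochondrially encoded genes were higher in heart for 6 of 13 in edgeR, while DESeq2 called 12, with mt-Co2 at 2.42 and mt-Co3 at 2.21 and a median of 1.12 (camera adjusted p = 0.0414; adjusted p = 0.585 with an estimated correlation). Of 21 nuclear-encoded respiratory chain genes only Cox4i1 (1.37) and Cox7b (1.28) passed the threshold, and 0 did in edgeR when adjusted over the list alone, against 3 at an unadjusted p under 0.05 and 3 in DESeq2. Their median was 0.39 (camera adjusted p = 0.201). Of 15 tricarboxylic acid cycle genes, Idh2 was higher in heart (1.93) and Idh3a in gastrocnemius (-0.68), the latter not when adjusted over the list alone, and the list's median of -0.06 and mean of 0.01 differed in sign (camera adjusted p = 0.657).

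Protein turnover and stress programs were mixed. Muscle atrophy genes were higher in gastrocnemius for 8 of 15, with myostatin Mstn at -7.27, Eda2r at -5.26, Gadd45a at -4.59 and the ubiquitin ligase Trim63 at -2.89, and 7 did not pass. The median was -0.93 (camera adjusted p = 0.00601; adjusted p = 0.407 with an estimated correlation). Proteasome genes were higher in gastrocnemius for 14 of 20, and for 17 when adjusted over the list alone, among them Psmc2 (-1.53) and Psmb7 (-1.50), with a median of -0.84 (camera adjusted p = 2.17e-05; adjusted p = 0.531 with an estimated correlation). Cytosolic ribosomal protein genes were higher in heart for 9 of 20, among them Rpl3 (2.61) and Rps3 (1.05), with a median of 0.85 (camera adjusted p = 0.00684; adjusted p = 0.632 with an estimated correlation). Glucocorticoid targets split into 2 higher in heart, the metallothioneins Mt2 (3.35, and less but still called without the letter C heart library) and Mt1 (2.90), and 7 in gastrocnemius, including Zbtb16 (-1.79) and Sgk1 (-1.76), of 11 (camera adjusted p = 0.0896). The circadian clock list had 2 of 17 higher in heart, Npas2 (1.70) and Hlf, and 7 in gastrocnemius, including Arntl (-3.15) and Nfil3 (-2.37) (camera adjusted p = 0.105). The sampling time is not stated in the labels. Immediate early genes had 4 of 17 higher in heart, with Klf4 (1.94) and Maff (1.91), and 3 in gastrocnemius (2 when adjusted over the list alone), with Nr4a1 (-2.39) and Jun (-2.00) (camera adjusted p = 0.493). Heat shock proteins had 2 of 11 higher in heart, Hsp90aa1 (1.56) and Dnajb1 (1.49), and Hsph1 (-1.21) in gastrocnemius (camera adjusted p = 0.493).

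The unfolded protein and integrated stress response list had 5 of 14 higher in heart (6 when adjusted over the list alone), with Phgdh (2.58) and Asns (1.77), and 5 in gastrocnemius, with Chac1 (-6.05) and Atf4 (-1.99). Its median of 0.10 and mean of -0.16 differed in sign (camera adjusted p = 0.764). The oxidative stress response list had 3 of 12 higher in heart, with Gpx1 (1.26) and Slc7a11 among them, and 2 in gastrocnemius, Txnrd1 (-1.87) and Srxn1 (-1.51) (camera adjusted p = 0.977). Cell cycle genes were higher in heart for 6 of 10, with Mcm6 (2.79), Mcm5 (1.79) and Mki67 (1.76), and the list was not called (camera adjusted p = 0.105).

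Most matrix, macrophage, endothelial and inflammation genes were higher in heart. Extracellular matrix genes were higher in heart for 18 of 20, among them Ccn2 (4.46), Bgn (3.80) and Postn (3.38), with a median of 1.91 (camera adjusted p = 1.43e-06; adjusted p = 0.378 with an estimated correlation). All 10 fibroblast genes were higher in heart, with Tcf21 at least 125.6-fold, Pi16 at 2.89, Lum at 2.88 and Dcn at 2.63, and a median of 2.32 (camera adjusted p = 2.17e-05; adjusted p = 0.378 with an estimated correlation). All 12 macrophage genes were higher, led by Fcgr1 (4.92), C1qb (4.37) and Adgre1 (3.90), with a median of 3.62 (camera adjusted p = 9.95e-07; adjusted p = 0.31 with an estimated correlation). All 12 endothelial genes were higher, led by Eng (3.41), Emcn (2.88) and Vwf (2.49), with a median of 1.84 (camera adjusted p = 6.18e-06; adjusted p = 0.112 with an estimated correlation). Inflammation genes were higher in heart for 11 of 12 (12 when adjusted over the list alone). Among them Ccl7, with 2 counts in gastrocnemius, had a ratio of 379 (105 to 3136), Ccl2 stood at 7.29 and Ptgs2 at 6.10, and the list's median was 3.32 (camera adjusted p = 9.9e-06; adjusted p = 0.301 with an estimated correlation). Without the letter C heart library Ccl7 fell from 8.48 to 6.10 and Ccl2 to 4.96, both still called, and DESeq2 gave neither an adjusted p. Interferon response genes were higher in heart for 17 of 19, including Ifit2 (2.96), Oas1a (2.83) and Isg15 (2.79), with a median of 2.14 (camera adjusted p = 7.13e-06; adjusted p = 0.32 with an estimated correlation). All 5 erythroid genes were higher in heart, led by Hba-a2 (7.32) and Hba-a1 (6.16), near-identical copies, with a median of 6.14 (camera adjusted p = 0.00833; adjusted p = 0.489 with an estimated correlation). Without the letter C heart library Hba-a2 fell to 4.34 and Hba-a1 to 4.49, both still called.

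All 6 ventricular cardiomyocyte markers were higher in heart, with Fhl2 at 7.91 and Irx4 at least 46.5-fold. The fitted median was 6.23, or 5.045 with bounds (camera adjusted p = 1.89e-05; adjusted p = 0.261 with an estimated correlation). Atrial cardiomyocyte markers were higher for 4 of 5 tested (5 when adjusted over the list alone), with Myl4 at 6.30 and Dkk3 at 3.57, and camera did not call the list (adjusted p = 0.0585). With the title letter as a block neither gene passed (adjusted p = 0.165 and 0.119), nor with limma-trend (0.294 and 0.127). Smooth muscle and pericyte markers were higher for 5 of 9, with Cnn1 at 4.39 and Acta2 at 2.32, and lower for 1 (camera adjusted p = 0.159). In gastrocnemius, 3 of 8 Schwann cell and nerve markers were higher, including Ncmap (-3.34) and Ngfr (-2.95), and Pmp22 (1.19) was higher in heart (camera adjusted p = 0.267). Of 4 satellite cell markers, Pax7 was at least 13.9-fold higher in gastrocnemius, Myf5 had 1 count in heart and a ratio of 169 (29.8 to 6707), and Chodl stood at -5.18. The fourth, Sdc4, did not differ past the threshold. Among brown adipocyte markers Cidea was higher in heart (4.34) and Elovl3 in gastrocnemius (-3.57), and 4 of 6 did not pass (camera adjusted p = 0.493). White adipocyte markers passed for 0 of 7 genes in edgeR, with 1 at an unadjusted p under 0.05 and 0 in DESeq2 (camera adjusted p = 0.507), with Cidec at 20.5 ± 18.1 CPM in heart and 5.74 ± 6.17 in gastrocnemius. Lymphocyte markers also passed for 0 of 7 in edgeR, with 0 unadjusted and 0 in DESeq2 (camera adjusted p = 0.425). For Cd79a and Cd79b the order of the tissues turned on the letter C gastrocnemius library and on the model. Cd79a stood at -1.31 with that library and at 7.07 without it, and Cd79b at -1.46 and 2.47. With the library kept, Cd79a was at 0.40 with the letter as a block and 0.92 with limma-trend, and Cd79b near 0 and at 0.20, none of them past the threshold. Too few members were measured for a camera test of neutrophil markers (Csf3r, 3.54), epicardial and mesothelial markers (Wt1, at least 25.4-fold higher in heart, and Krt19, 3.39, adjusted p = 0.129 with the letter as a block) and tendon markers. Of the 4 tendon markers, Comp was higher in heart (4.77), and Scx, Fmod and Thbs4 did not pass. The lung epithelium marker Sftpb (adjusted p = 0.841) and Xist of the sex list (-0.65, adjusted p = 0.2) did not differ past the threshold in edgeR. With the letter as a block Xist passed at -0.57 (adjusted p = 0.0447).

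Of 39 lists tested, camera called 23 with its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.11. Splits of the libraries that mixed the tissues gave 16 to 27 lists with the preset correlation. The number of lists called thus does not set the tissues apart. The median log2 fold change of all tested genes was 0.0461.

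**Figure D2:**
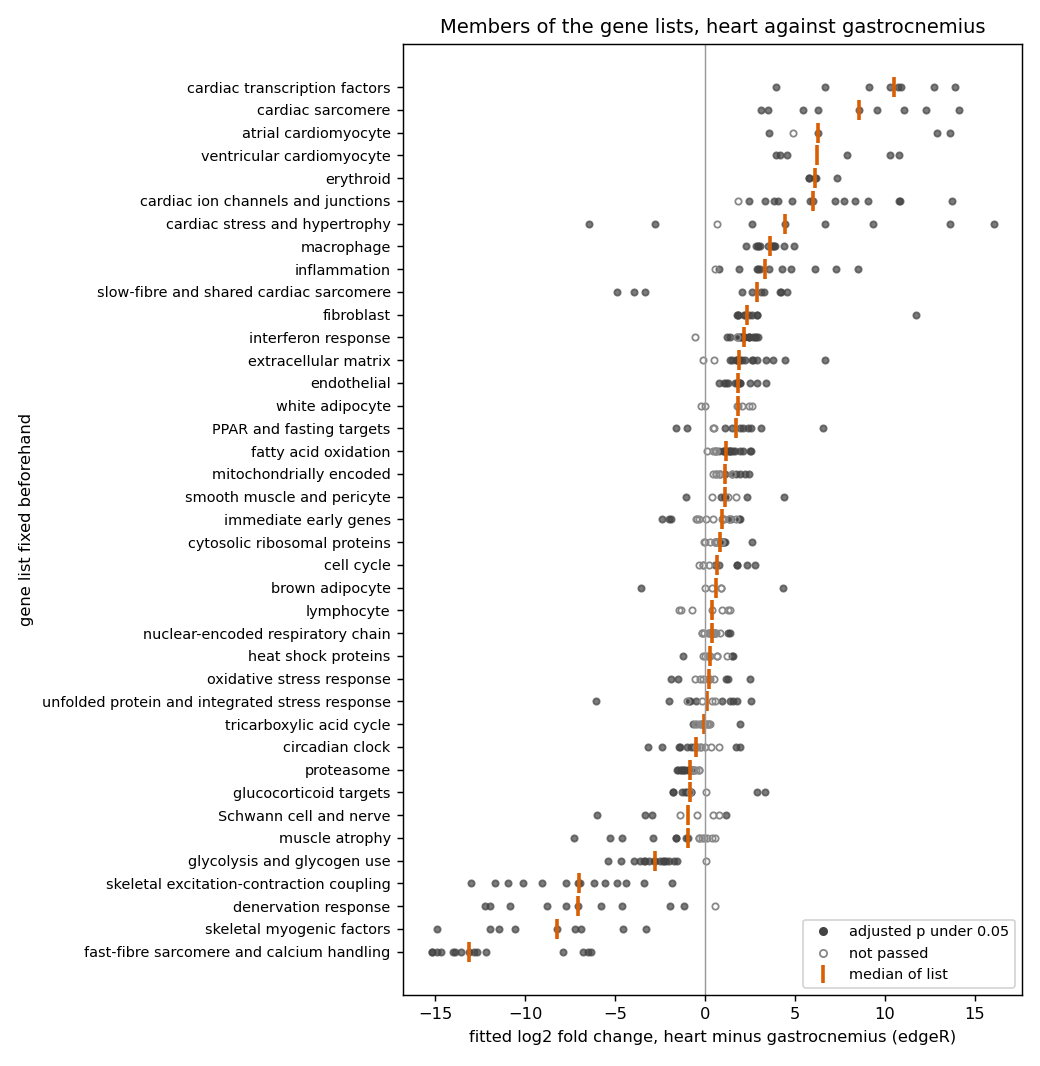
Fitted log2 fold change of heart over gastrocnemius (x axis) for the members of 39 gene lists (y axis), filled where the adjusted p was under 0.05, with the median of each list as a bar. Medians run from 10.5 for cardiac transcription factors to -13.1 for fast-fibre genes, and fitted values of genes at 0 counts in a tissue depend on the prior count.

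The title letters were compared across both tissues together. Against letter C, both M and Z libraries had less haemoglobin RNA and more of the myosin phosphatase subunit Ppp1r12b. Chemokine RNA was lower in heart and Igfn1 higher in gastrocnemius, but none of these genes passed in edgeR after adjustment. For M against C, Ccl7 stood at -3.86 (2, 0 and 0 counts in gastrocnemius C, M and Z), Ccl2 at -3.56 (4, 1 and 0 counts), Cops9 at -1.33 (SE 0.15) and the respiratory complex III assembly gene Uqcc2 at -1.40 (SE 0.16). On the other side were Igfn1 (6.39, at 0 in all heart libraries), Mybphl (5.80, at 0 in all gastrocnemius libraries), Adamts8 (3.53), Aox1 (1.44, SE 0.16) and Ppp1r12b (1.32, SE 0.16). For example, Cops9 had 151, 61.0 and 71.3 CPM in the heart libraries of C, M and Z and 118, 46.5 and 56.4 in those of gastrocnemius. For Z against C, Ccl2 stood at -3.72, Ccl7 at -3.69, the haemoglobin gene Hbb-bt at -3.13, March5 at -2.55 and Itgb6 at -2.32, and Mybphl (5.21), Igfn1 (4.97), Rps18 (1.79), Ppp1r12b (1.45) and Leng8 (1.38) were on the other side. For M against Z, Rps18 was lower (-2.53, SE 0.16), with 27.2 CPM in heart M and 163 in heart Z, and 21.3 and 118 in gastrocnemius. Rpl21 (-6.43), Gbp2b (-4.15) and Acad12 (-0.85) lay on the same side, and Baiap2l1 (3.45, with 4, 1 and 1 counts in gastrocnemius C, M and Z), March5 (2.36), Itgb6 (1.57), Abca6 (1.27) and Slc47a1 (0.91) on the other. Rps18 and Rpl21 have near-identical pseudogene copies, so their counts are uncertain.

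Over all genes, edgeR called 0 genes at an adjusted p of 0.05 in each of the 3 letter comparisons, with smallest adjusted p-values of 0.121, 0.129 and 0.0838 for M against C, Z against C and M against Z. At an unadjusted p under 0.05 there were 3295, 3315 and 309 genes, where chance alone gives 831, and DESeq2 called 976, 954 and 8 after adjustment. An edgeR test for any letter difference gave 0 adjusted and 2732 unadjusted genes. With the gastrocnemius labels matched to other heart letters, the unadjusted number was 2667 when M and Z were exchanged and 244 to 506 in the other 4 matches. Whether the letter result hangs on single libraries could not be decided. Leaving out a library leaves its letter with a single library, so gene counts after an omission do not measure that letter's spread.

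Among gene lists, camera called ribosomal, respiratory and immediate early genes as lower in M and Z than in C, but with an estimated correlation it called none of them (adjusted p = 0.951 for M and 0.882 for Z). Within heart alone the ribosomal list lay inside the central 95% of random lists (percentiles 13.58 for M and 8.22 for Z, or 71.76 and 50.05 matched on length). Within gastrocnemius the list lay below that range for M (-0.734) and Z (-0.594). Its genes are short, and the letter C libraries carry a trend towards short transcripts (given below). With M against C, 18 of 20 cytosolic ribosomal protein genes passed when adjusted over the list alone, 17 of them lower in M, with a median of -0.70 (camera adjusted p = 3.12e-09), as did 6 of 21 nuclear-encoded respiratory chain genes (-0.54, camera adjusted p = 4.8e-05) and all 5 erythroid genes (-1.82, camera adjusted p = 0.00285). Camera also called the proteasome (-0.56, adjusted p = 3.08e-07), immediate early genes (-0.73, adjusted p = 4.8e-05), heat shock proteins (adjusted p = 0.00285), lymphocyte markers (-2.60, adjusted p = 0.0051), interferon response (adjusted p = 0.0183) and fatty acid oxidation (adjusted p = 0.0341) as lower in M. Fast-fibre genes were called as higher (0.77, adjusted p = 0.0183). In single tissues, the lymphocyte and fatty acid oxidation lists lay inside the central 95% of random lists in heart for M. In gastrocnemius the respiratory chain, erythroid, heat shock, fatty acid oxidation and fast-fibre lists did. All 10 calls were lost, at adjusted p = 0.951 with an estimated correlation and 0.954 for fatty acid oxidation. In simulated letter counts that setting also missed a planted list. Such losses between letters therefore do not decide whether a list differs.

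With Z against C, 12 of 17 immediate early genes passed when adjusted over the list alone, with a median of -1.47 (camera adjusted p = 9.51e-10; adjusted p = 0.882 with an estimated correlation). The same held for 9 of 20 ribosomal protein genes (-0.55, adjusted p = 7.21e-07), 6 of 21 respiratory chain genes (-0.62, adjusted p = 1.09e-05), all 5 erythroid genes (-2.99, adjusted p = 2.83e-04), 6 of 12 inflammation genes (-0.91, adjusted p = 0.00191), 4 of 12 macrophage markers (-0.85, adjusted p = 5.54e-04) and 4 of 13 mitochondrially encoded genes (adjusted p = 0.0329). Camera further called extracellular matrix (-0.60, adjusted p = 2.83e-04), interferon response (adjusted p = 0.00191), heat shock proteins (adjusted p = 0.00402), fibroblast markers (adjusted p = 0.00676), fatty acid oxidation (adjusted p = 0.00731), the proteasome (adjusted p = 0.00874) and lymphocyte markers (adjusted p = 0.0138), all lower in Z. In heart the lymphocyte median was on the other side (0.14, percentile 54.1), and the extracellular matrix, fibroblast and fatty acid oxidation lists also lay inside the central 95% for Z. In gastrocnemius the proteasome, heat shock and mitochondrially encoded lists did. The 14 calls were lost, at adjusted p = 0.882 with an estimated correlation.

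With M against Z, fibroblast (0.60, camera adjusted p = 3.31e-08), immediate early (0.58, adjusted p = 1.24e-08), extracellular matrix (0.53, adjusted p = 1.99e-07), macrophage (adjusted p = 5.35e-06) and inflammation lists (adjusted p = 0.0035) were called as higher in M, although 0 of their genes passed in edgeR when adjusted over the list alone, and all were lost with an estimated correlation (adjusted p = 0.893). At an unadjusted p under 0.05 there were 3 fibroblast, 7 immediate early, 2 matrix, 2 macrophage and 1 inflammation genes, and DESeq2 called 0 of them. The proteasome (-0.28, adjusted p = 3.13e-08), muscle atrophy (-0.39, adjusted p = 1.85e-05) and ribosomal protein lists (adjusted p = 0.00604) were called as lower. Slow-fibre (adjusted p = 0.00107), fast-fibre (adjusted p = 0.0035) and erythroid calls (adjusted p = 0.024) reversed when 1 library was left out: slow-fibre without either the M or the Z gastrocnemius library (adjusted p = 0.0685 and 0.762), fast-fibre without the M heart library (0.526) and erythroid without the M gastrocnemius library (0.345). In heart alone the proteasome, muscle atrophy and ribosomal lists lay inside the central 95%, and in gastrocnemius the ribosomal, inflammation and fast-fibre lists did. The 11 calls were lost, at adjusted p = 0.893 with an estimated correlation. Each letter has 1 library per tissue, and comparisons with C share the same C libraries, so M and Z can resemble each other through C alone.

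Within heart, the letter C library lacked atrial transcripts that were abundant in the M and Z libraries. Myl7, the atrial regulatory myosin light chain gene, had 0 counts in C, 37772 in M and 32396 in Z, at least 9858-fold and at least 9704-fold higher. Sln, the sarcolipin gene, had 0, 15894 and 10065 counts (at least 4148-fold and at least 3015-fold). Myl4 had 12, 28829 and 24132 counts, ratios of 1881 and 1807, and the atrial growth factor gene Bmp10 had 1, 2464 and 6361 counts, ratios of 1929 (346 to 76230) and 5716 (1026 to 225800). All 7 atrial markers were at least 2-fold higher in M and in Z, with medians of 6.77 and 8.33, both at percentile 100 of random lists. Cardiac ion channels and junctions lay at 0.79 and 0.72 (percentile 100 for both), with Kcnj5 at 577 counts in C and 2767 in M and Gja5 at 69 and 584. Epicardial and mesothelial genes such as Upk3b (0, 865 and 947 counts in C, M and Z) and Msln (0 and 303 in C and M) were higher too, with medians of 2.82 and 3.39, as were white adipocyte genes such as Adipoq (18 and 649 counts in C and M), with medians of 3.56 and 3.32 (percentile 100 for all).

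The C heart library in turn held more blood, chemokine, stress and immediate early RNA. Haemoglobin Hba-a2 had 2154 counts in C and 59 in M (46.6-fold), and the 6 erythroid genes had medians of -2.78 for M and -3.06 for Z. Chemokines Ccl7 (806 against 71 counts in M, 14.5-fold) and Ccl2 (802 against 80, 12.8-fold), with Timp1 (1132 against 97, 14.9-fold), were higher in C, and the inflammation list lay at -0.88 for M and -1.03 for Z. Neutrophil genes lay at -1.83 and -1.79, and S100a9 had 96 counts in C and 11 in M. Nppb had 15565 counts in C, 3447 in M and 8062 in Z, and the stress list lay at -1.03 (percentile 0.08) and -0.73 (percentile 1.29). Immediate early genes lay at -0.91 and -1.18 (percentile 0 for both), with Fos at 413, 159 and 76 counts in C, M and Z. Hspa1a, a heat-inducible chaperone gene with a near-identical copy, had 236 counts in C and 24 in M, and heat shock proteins lay at -0.88 and -0.78. Respiratory chain genes were lower in M (-1.04, percentile 0.02), with 11 of 21 at least 2-fold lower and Cox5a at 6573 against 15674 counts, and in Z (-0.67, percentile 1.46). Interferon response genes lay at -0.49 and -0.40. Proteasome genes lay at -0.65 and -0.52 (percentiles 0.32 and 0.31), but at percentiles 18.33 and 22.82 of random lists matched also on transcript length.

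Other lists set single heart pairs apart. Fast-fibre genes were higher in M than in C (1.24, percentile 100), with Myh4 at 80 counts in M and 1 in Z. Schwann cell genes were higher in M (0.84) and Z (0.90), tendon genes in M (1.34, with Fmod at 704 against 2 counts, a ratio of 276 with interval 76.0 to 2280) and Z (0.89), and fibroblast genes in M (0.30). Smooth muscle genes were higher in Z (0.80), where Myh11 had 1031 counts against 57 in C and Cnn1 had 267 against 3, a ratio of 80.0 (27.1 to 390). PPAR and fasting targets lay at 0.21 in M and 0.53 in Z, with Pdk4 at 30647 counts in Z and 14416 in C. Skeletal myogenic factors (1.13) and clock genes (0.34) were higher in Z, but both lay inside the central 95% when matched on length (percentiles 97.48 and 92.77), and macrophage (-0.58) and mitochondrially encoded genes (-0.79, at percentile 31.13 when matched on length) were lower. M and Z differed less. Immediate early genes were higher in M (0.54), as were fast-fibre (0.44), fibroblast (0.33) and macrophage genes (0.25), and the slow-fibre (-0.37), lymphocyte (-0.58), epicardial (-0.51), ventricular (-0.35), fatty acid oxidation (-0.27), respiratory (-0.25) and tricarboxylic acid cycle lists (-0.24) were lower. Baiap2l1 had 2783 counts in M and 190 in Z, H2-K1, a histocompatibility gene with close copies, 600 and 4401, Gbp2b 16 and 240, and Ifi202b 216 and 2, a ratio of 94.1 (25.7 to 782).

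Between the heart libraries, 967 of 9168 genes differed at least 2-fold for M and C, 424 of them higher in M (43.8%), 745 of 9074 for Z and C, 405 higher in Z (54.4%), and 84 of 8930 for M and Z (46.4% higher in M). With the length trend removed, a setting chosen after the data were seen, the shares were 59.0%, 63.1% and 53.4%, so the majority changed side for M and C and for M and Z. With CPM by total count the first pair gave 1402 genes, 88.0% higher in M, and the second 1100, 87.8% higher in Z, because the median of all genes shifted by 0.377 and 0.313 on the log2 scale. No list outside the central 95% of random lists changed its sign with that scaling, and values here are relative to the TMM scale. Of 42 lists, 18, 21 and 17 lay outside the central 95% for M against C, Z against C and M against Z.

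**Figure D3:**
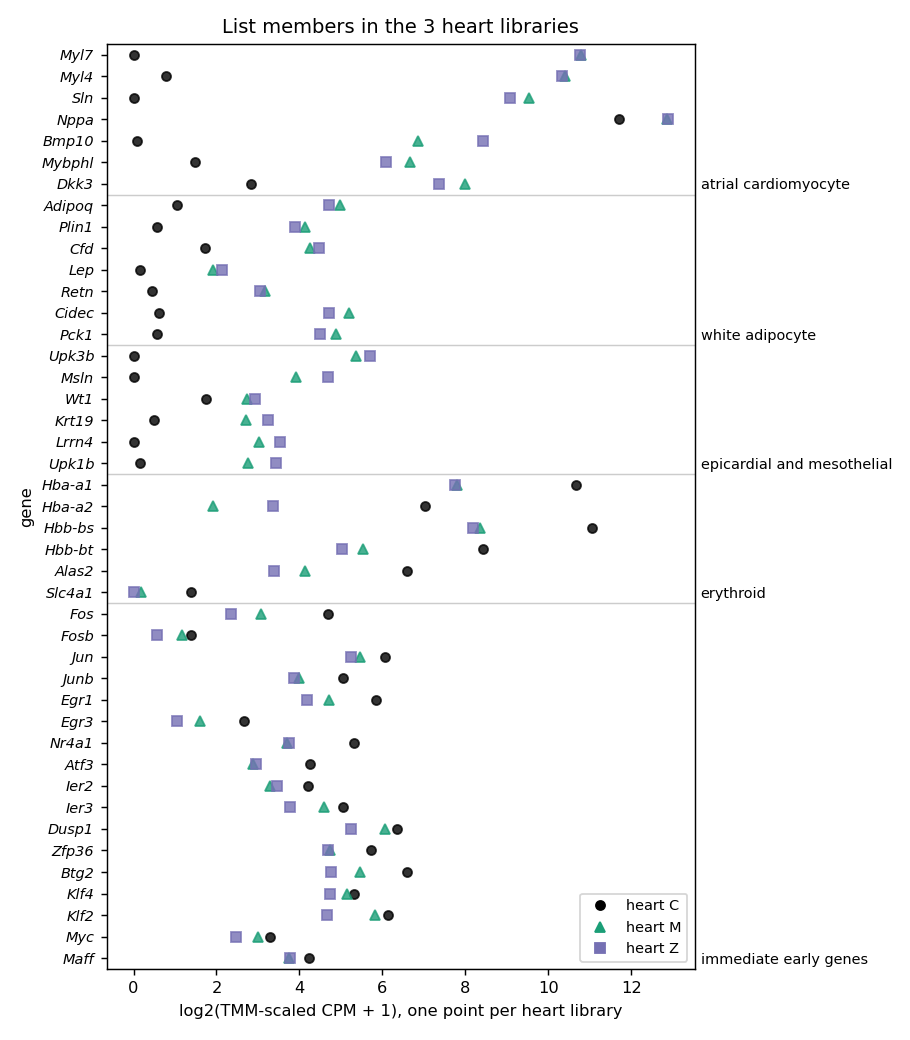
Log2 of TMM-scaled CPM plus 1 (x axis) for the members of 5 gene lists (y axis) in the heart libraries of letters C, M and Z, with 1 library per letter and so no error bars. Atrial genes such as Myl7 stand at 0 counts in C and 37772 in M, while haemoglobin and immediate early genes are highest in C.

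Within gastrocnemius, B cell, adipocyte and immediate early RNA was higher in the letter C library. The immunoglobulin gene Ighd had 329 counts in C, 0 in M (at least 106-fold) and 1 in Z, and Cd79a had 112 in C and 0 in M (at least 36.2-fold). All 6 lymphocyte genes were at least 2-fold lower in M and in Z, with medians of -2.46 and -2.41 (percentile 0 for both). White adipocyte genes lay at -1.31 for M and -2.71 for Z (percentile 0 for both), where Adipoq had 185 counts in C and 7 in Z and Cidec 194 and 5. Immediate early genes lay at -0.45 and -1.03, with Fos at 934 counts in C and 255 in Z and Klf2 at 588 and 112. Glucocorticoid targets (-0.49 and -0.65; Cebpd at 1274 counts in C and 387 in M), interferon response genes (-0.43 and -0.63; Psmb9 at 106 and 23) and ribosomal protein genes (-0.73 and -0.59) were lower in M and Z as well. For ribosomal genes in Z, random lists matched also on length put the median at percentile 5.1, inside the central 95%.

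Slow-fibre sarcomere genes set the M gastrocnemius library apart, while the cardiac sarcomere (0.35) and fast-fibre lists (0.124) lay inside the central 95% against C. Slow-fibre genes were higher in M than in C (0.65, percentile 99.95), with the slow myosin gene Myh7 at 12914 against 3206 counts and Atp2a2 at 9557 against 3227. Igfn1 had 5919 counts in M, 72 in C and 2178 in Z, the cardiac actin gene Actc1 8096 in M and 1180 in C, the mitochondrial gene Mss51 6996 in M, 1021 in C and 29696 in Z, and Kbtbd12 3878 in M and 534 in C. Cardiac stress (0.68), smooth muscle (0.51) and tendon genes (1.16) were higher in M than in C, and proteasome genes were lower (-0.39, percentile 0.33, or 28.87 when matched on length). In Z against C, extracellular matrix (-0.94), fibroblast (-1.22), Schwann cell (-1.17), erythroid (-1.70), macrophage (-0.86), inflammation (-0.66), PPAR (-0.65), respiratory chain (-0.57) and fatty acid oxidation genes (-0.50) were lower. Col3a1 had 265 counts in Z and 1045 in C, Fabp3 7647 and 16258, the adipsin gene Cfd 18 and 475, and the transcription factor genes Tbx1 12 and 400 and Irx5 0 and 264 (at least 84.4-fold lower in Z).

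Between M and Z in gastrocnemius, slow-fibre genes were higher in M (1.42, percentile 100), 8 of 10 at least 2-fold, with Myh7 at 12914 against 3946 counts and Tnnc1 at 5235 against 1538. Extracellular matrix and fibroblast genes (0.89 for both), white adipocyte (1.78), Schwann cell (1.37), erythroid (1.29), tendon (0.72), cardiac sarcomere (0.62), immediate early (0.61), ventricular (0.58), fatty acid oxidation (0.46), macrophage (0.45), mitochondrially encoded (0.40), PPAR (0.39), respiratory (0.33), smooth muscle (0.27), tricarboxylic acid cycle (0.26) and endothelial genes (0.22) were higher in M too. Lower in M were the denervation response (-0.47; Musk at 72 against 219 counts), muscle atrophy (-0.46; Eda2r at 1228 against 4054 and Gadd45a at 1959 against 4701), proteasome (-0.40) and excitation-contraction coupling lists (-0.32). In gastrocnemius 508 of 8510 genes differed at least 2-fold for M and C (42.5% higher in M), 788 of 8538 for Z and C (43.8% higher in Z) and 231 of 8318 for M and Z (63.6% higher in M). With the length trend removed the shares were 62.1%, 44.0% and 72.9%, so the majority changed side for M and C. With CPM by total count the higher shares for M and C and for Z and C were 30.4% and 29.6%. Of 40 lists, 11, 15 and 22 lay outside the central 95% of random lists in the same order.

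**Figure D4:**
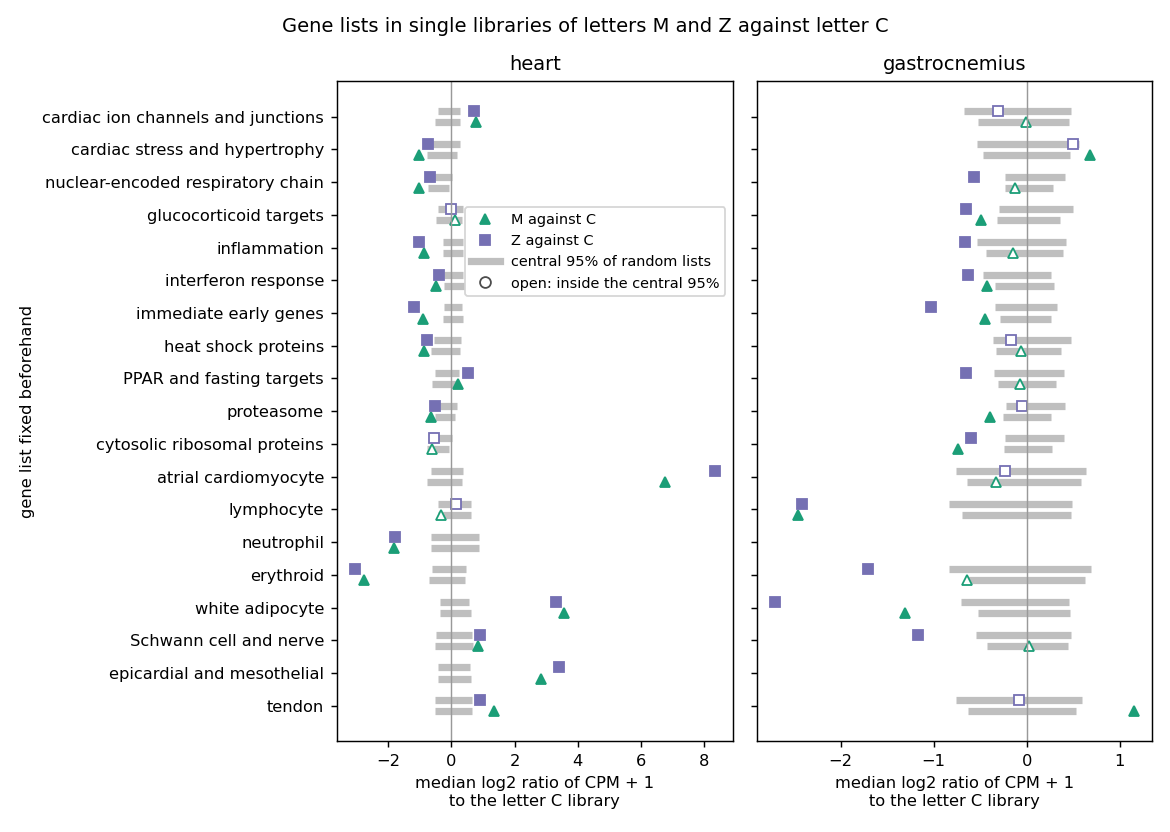
Median log2 ratio of CPM plus 1 to the letter C library (x axes, of different range) for gene lists (y axis) in heart and gastrocnemius, with grey bars for the central 95% of random lists and open markers inside it. White adipocyte genes lie at 3.56 in heart and at -1.31 in gastrocnemius for M against C, while immediate early genes lie below 0 in both tissues.

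Longer transcripts were relatively higher in M and Z than in C in both tissues. In heart, Spearman's rho across genes between the log2 difference and transcript length was 0.364 for M against C and for Z against C, and in gastrocnemius 0.284 and 0.217. For M against Z it was 0.0654 and 0.033. Genes up to 789 bp had a median log2 difference of -0.33 in heart M against C, and genes from 6411 bp one of 0.48. Long genes such as Ryr2, Myh6, Ppp1r12b and Aox1 may carry part of this trend, as may short ones such as Cox5a, Cops9, Uqcc2 and the ribosomal protein genes. The part of the trend in each gene's difference is not given here. With the trend as an offset in edgeR, genes at an unadjusted p under 0.05 fell from 3295 to 2292 for M against C. For Z against C they fell from 3315 to 2322. Only the percentiles given above as matched on length take it into account (ribosomal, proteasome, mitochondrially encoded, skeletal myogenic and clock lists). The percentiles of the other lists, such as ion channels and the respiratory chain, do not. Between tissues, the fold changes of the letters correlated across 12429 genes at r = 0.443 for M against C, 0.341 for Z against C and 0.00359 for M against Z, and genes are not independent replicates.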

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

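White adipocyte genes lay on opposite sides in the tissues. For letter M against C their median log2 difference was 3.56 in heart and -1.31 in gastrocnemius, and for Z against C it was 3.32 and -2.71. Schwann cell and nerve genes stood at 0.899 in heart and -1.17 in gastrocnemius for Z against C, and PPAR and fasting targets at 0.529 and -0.649. Cardiac stress and hypertrophy genes stood at -1.03 in heart and 0.677 in gastrocnemius for M against C. For M against Z, the slow-fibre and shared cardiac sarcomere genes stood at -0.369 in heart and 1.42 in gastrocnemius, and ventricular cardiomyocyte genes at -0.35 and 0.58. Fuel genes followed the same order for M against Z, with fatty acid oxidation at -0.268 and 0.458, the nuclear-encoded respiratory chain at -0.245 and 0.331, and the tricarboxylic acid cycle at -0.244 and 0.261. These lists are named because both medians lay outside the central 95% of random lists, on opposite sides in the tissues. Each value compares 1 library with another, so the difference between the tissues was not tested, and no explanation was weighed for it.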

How the results depend on the processing

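Omission of both letter C libraries, removal of the transcript length trend and random lists matched also on length were chosen after the data were seen, and the other alternatives before. Between heart and gastrocnemius, 6476 to 10727 genes were called under every alternative but the filter of 10 CPM in 3 libraries, which gave 4902 because fewer genes were tested. Leaving out each library in turn gave 6824 to 9236, DESeq2 size factors 8483, no filter 9183, mitochondrially encoded genes left out 8596, a 2-fold minimum 6476, and omission of both letter C libraries 10727. With the title letter as a block edgeR called 9461 genes and camera 23 lists, which changed no call of a list. Of the genes named, Myl4, Dkk3 and Krt19 lost their call with the block and Xist gained it. The letters were not counted as pairing the libraries in the main fit, because the labels' protocols give no design. As a separate check, the deviations from the tissue mean correlated across genes between the tissues at 0.215 for C, 0.205 for M and 0.0356 for Z. Heart Z correlated better with gastrocnemius M (0.135) than with gastrocnemius Z. Pearson's r was fixed beforehand for this check. Spearman's rho was 0.344, 0.274 and 0.136 for the same letters and 0.211 for heart Z with gastrocnemius M, so pairing stays open. Over genes with at least 10 CPM on average the correlations were 0.369, 0.279 and 0.119, and the cause was not tested.

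For the letters, where the main edgeR test called 0 genes in each comparison, no filter gave 329 genes for M against C, 226 for Z against C and 4 for M against Z, and DESeq2 gave 976, 954 and 8. Leaving out each library in turn gave 0 to 367, 0 to 556 and 0 to 12 genes, with the highest values without the heart library of letter C. The cause was not tested. With the length trend as an offset there were again 0 genes in edgeR, with 2292, 2322 and 313 at an unadjusted p under 0.05.

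With an estimated correlation camera called 0 lists for the tissues and 0 in each letter comparison, in place of 23, 10, 14 and 11. Why the calls were lost was not tested. In the simulated letter design that setting also missed the planted 2-fold list, although its genes were independent. Lost calls between letters therefore do not decide whether a list differs. In the simulated tissue design the planted list was called. Leaving out each library in turn gave 23 to 26 lists for the tissues, 8 to 18 for M against C, 11 to 22 for Z against C and 13 to 20 for M against Z, and the cause was not tested. At fewest, 5 of the 10 calls for M against C stayed (without heart C), 9 of the 14 for Z against C (without heart C or gastrocnemius Z) and 6 of the 11 for M against Z (without gastrocnemius Z). Removal of the length trend gave 11, 13 and 11. In the letter comparisons each omission left a letter with 1 library, so the list counts after an omission do not measure that letter's spread. For M against Z the direction of some lists reversed when 1 library was left out. The adjusted p over these omissions ran from 7.49e-16 to 0.762 for slow-fibre genes, 3.74e-16 to 0.526 for fast-fibre genes and 1.2e-07 to 0.345 for erythroid genes. Between tissues, Cd79a ran from -1.91 to 7.07 and Cd79b from -2.08 to 2.47 (log2), and Cd79b stood at 2.69 without both letter C libraries, since nearly all its gastrocnemius counts came from that letter.

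Single-library counts of genes at least 2-fold apart moved with the settings. A pseudocount of 5 CPM, which shrinks ratios at low values, gave 633, 485 and 54 genes in heart for M against C, Z against C and M against Z and 297, 516 and 148 in gastrocnemius. A minimum of 1 CPM, which admits more genes, gave 1644, 1365 and 188 in heart and 1000, 1576 and 506 in gastrocnemius. Removal of the length trend gave 627 genes for heart M against C, and the cause of the fall was the trend removed.

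Among single genes named between tissues, 2047 values over all alternatives kept their side of the threshold, 68 lost their call, 5 gained it and 3 reversed with a call. Among the 2047, Cd79a, Cd79b and Sftpb changed direction under some alternatives without a call on either side. Leaving out 1 library or another lost the call of Cox4i1, Cox7b, Idh3a, Zbtb16, Npas2, Oas1a, Hsph1, Phgdh, Srxn1, Mki67, Rps3, Myl4, Dkk3, Cnn1, Elovl3, Pmp22 and Krt19. Cidec and Adipoq passed without both letter C libraries. For lists 547 kept their side, 102 lost their call, 13 gained it, and 4 changed direction and lost it. For genes named between letters 275 kept their side and 67 gained a call. Among the 275, Mybphl, Igfn1 and Baiap2l1 changed direction without a call when 1 library was left out. The values between letters include such omissions, which do not measure the spread of the letter left with 1 library. Depth limits genes near the floor of 0.140 to 0.201 CPM, where only bounds can be given.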

Other observations

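Xist was lower in the letter C library of both tissues. It had 2771 counts in heart C, 5768 in heart M and 5523 in heart Z, and 3071, 5914 and 8280 in gastrocnemius. These counts are not scaled, and the TMM factors in heart were 0.972 for C, 1.25 for M and 1.20 for Z, so they widen the heart difference. The part of the transcript length trend in the Xist difference was not tested. Sbk2, a kinase gene, had 34 counts in heart C, 1174 in M and 480 in Z, but 1965, 1471 and 567 in gastrocnemius. Scd1, a fatty acid desaturase gene, had 224, 2039 and 651 in heart and 481, 252 and 52 in gastrocnemius. For both genes letter C was thus lowest in heart but highest in gastrocnemius. These genes were chosen after their values were seen. Among glucocorticoid targets, 4 of 11 passed for M against C and 6 of 11 for Z against C in edgeR when adjusted over the list alone, although camera did not call the list (adjusted p = 0.159 and 0.134).

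The tests of the length trend on atrial genes, of RNA quality, of chance in the M and Z genes and of linked blocks were chosen after the results were seen, and the others before. No biological explanation for a difference between the letters as groups was tested, because their meaning is not given, and such a difference stays open throughout. For the tissues, 1 of the 10 splits of the 6 libraries into 3 and 3 gave as many as the real 8435 genes, and the highest other split gave 0. For lists the real split gave 23 and the highest other 27, with 4 of 10 splits at 23 or more. In both cases 10 splits are too few for a share under 0.05. For lists, the splits that mixed the tissues gave 16 to 27 calls. The number of lists called with the preset correlation thus does not set the real split apart.

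Atrial genes such as Myl7 and Sln were at 0 counts in the heart library of letter C. The length trend between the libraries is argued against as the whole cause, since with that trend removed the lowest of the 7 atrial genes still stood at 1.5 (log2) over letter C. Less atrial and sinus node tissue in that library may account for it. In a separate list of 12 such genes, all of them detected in letter C, 11 were higher in M and in Z, with medians of 0.73 and 0.65 (percentiles 99.98 and 99.93), among them Cacna1g (1.67, 11.6 and 10.9 CPM in C, M and Z) and Pam (711, 1920 and 1660), while Kcna5 was lower (-0.88 and -0.96). The lower median of 0.651 fell between the bounds set beforehand, at least 1 for this explanation and under 0.5 against it, so it cannot be told apart from others.

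Short transcripts were relatively higher in the letter C libraries of both tissues. GC content is argued against, since over 10 groups of genes of like GC content the lowest of 4 median rank correlations of the log2 difference with length was 0.203. The lowest single group had 0.154. Ribosomal, proteasome and mitochondrial protein genes as the only source are argued against too, with a lowest correlation of 0.199 without them, far above what that explanation allows although just under the bound of 0.2 set beforehand. A difference in RNA quality or library preparation was not tested by a separate value. Its number of 0.217 is only the lowest of the 4 correlations that make up the pattern, and it goes with the letter, so letter and quality cannot be told apart.

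Between letters M and Z, of 13706 genes with at least 1 CPM in the higher library of both tissues, 23 were at least 2-fold apart in the same direction in both tissues, among them Rpl21 (25 and 1912 counts in heart M and Z, 11 and 471 in gastrocnemius) and Rps18 (584 and 3056, 322 and 1759). Another 17 were apart in opposite directions, and chance differences stay open for the set (two-sided exact binomial p = 0.43). That test compares only the number of genes in each direction. It cannot decide about single genes such as Rps18, whose log2 difference was -2.54 in heart and -2.41 in gastrocnemius. Reads shared between near-identical copies may add to the set: 12 of its genes were pseudogenes or had a named pseudogene, above the central 95% of 10000 random sets, which reached 4, and Hmgb1-ps7 had 215 counts in heart M and 7 in heart Z. Sequence variants in linked blocks of the genome also stay open, since 3 genes, Rps18, H2-K1 and H2-K2, lay within 1 Mb of another, where random sets had a median of 0 and a central 95% up to 4. Overlapping genes were left out of that count. With them, counted afterwards, it was 5, above the same 4, but the added pair, Gm27194 and Wsb2-ps, could share reads.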
